A study of Mus musculus with 2 samples.

How the data were processed

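Poly(A) RNA from 2 libraries of empty-vector DC1940 cells stimulated with pIC was sequenced on an Illumina instrument, per the labels' protocols and the series' design text. The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.0, Cufflinks 2.2.1 and the genome build mm10. The deposited values are FPKM, read fragments scaled to transcript length and to the number of mapped fragments, computed by the authors, per the file headers. The table has 1 such value per gene for the stimulated condition, and how the 2 libraries were combined is not given in the sources used here. The name of the table's sheet calls its rows differentially expressed genes of unstimulated against stimulated cells. That is the submitters' naming, and the threshold, test and direction behind it are not given in the sources used here. The table held 0 columns of other samples, and 1 row of it was not used here.

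The tests planned before the data were examined assumed fold changes, q values or values per library. These were counts of calls by direction, the median log2 fold change of each gene list matched on expression, and the agreement of the 2 libraries. None of them could be run on 1 pooled FPKM value per gene. They were replaced by a test of shares and a description of levels, both chosen after the table had been seen. The 26 gene lists, with 493 distinct genes, were fixed before the data were examined. The genes named follow the rule fixed for this case: the 20 highest rows, up to 3 members of each list with the highest FPKM, and 16 genes always named where listed. Among these 16, Il10, Ccr7, Irf8, Batf3 and Ncor1 are not analysed here. Some genes that the rule names are not reported here.

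List members were matched to rows by symbol, with older symbols where the table uses them, and 269 (54.6%) were listed. The listed share of each list was compared with that of the genes of the other lists by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 26 lists at 0.05. The median FPKM of each list with 3 or more listed members was placed among the medians of 10000 random lists of the same size drawn from the table, as a description without a p-value. Other backgrounds, floors on the FPKM value and matching by accession were tried as alternatives, all chosen after the table had been seen. The place of list members in the row order was compared with lists matched on 10 bins of FPKM by an exact test.

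Row intervals are on mm10, with 1 added to starts that count from 0. Of 8010 RefSeq accessions in the table, 7963 were matched to the RefSeq table of GRCm38.p6. There were 4802 rows with accessions of 1 gene, 74 with several and 22 with none matched. Genes within an interval were taken from GENCODE M21. Some named rows with accessions of 1 gene had intervals that overlapped other protein-coding genes, such as those of Nfkbia, B2m, Cxcl10, Irf5 and Ppp1r15a. Reads shared with the overlapping genes were not measured. The table has 4893 symbols, of which 5 stand on 2 rows, and the higher value was used for these. The share test was tested on 100 simulated tables of the 26 lists. In them, the antiviral effectors, the largest list with 54 genes, had a listed share of 75% and the other lists 40%. The test called the raised list in 93% of the tables and 0.36% of unchanged lists. Its power for smaller lists or smaller differences in share was not simulated. The level description placed a list raised 8 times within the highest 2.5% in 100% of 20 simulated tables, and 2.47% of unchanged lists. The unchanged lists were drawn at random from the table's own values, so a share near 2.5% was set by construction. Depth is unknown, so no interval or detection limit is given. The computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.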

Results

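RNA sequencing of poly(A)-selected RNA was carried out on DC1940 cells, a C57BL/6 mouse line of CD8α+ dendritic cells, the cross-presenting type of conventional dendritic cell. The cells carried an empty vector and had been stimulated with pIC, a synthetic double-stranded RNA that activates the receptor TLR3. There was 1 group of 2 libraries. The table held 1 FPKM value per gene for the stimulated cells, the authors' own value over the group, so no value below has an SD or a number of replicates, and no difference could be set against the spread between replicates. The depth of the libraries is unknown. The duration of the stimulation was not stated for these libraries.

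The comparison named for the table was of unstimulated against stimulated cells, which asks which transcripts differ after pIC stimulation. The table listed 4898 gene rows as differing. The direction and size of each difference were not analysed here, so the values below are levels after stimulation. The median was 9.68 FPKM, with quartiles of 2.32 and 33.4. There were 470 rows (9.60%) at 100 FPKM or more, 689 (14.1%) under 1 FPKM and 5 listed at 0. Ccl5, which encodes a chemokine that attracts T cells, had the highest value of the listed protein-coding genes, at 12867 FPKM (mm10, chromosome 11, 83525779 to 83530518). Ccl22, a chemokine made by mature dendritic cells, followed at 7332 FPKM (chromosome 8, 94745684 to 94751388). The apolipoprotein L gene Apol7c stood at 3996 FPKM (chromosome 15, 77524867 to 77533315), and B2m, the light chain of MHC class I, at 3006. The poly(A)-binding protein gene Pabpc1 had 2806 FPKM, Marcksl1 2637, Ptms 2028, Tagln2 1984, Txn1 1430.3 and Basp1 1188.

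The 20 highest rows took 32.2% of the FPKM summed over the listed rows. Among them were 2 short RNAs. The small nucleolar RNA Snord16a was the highest row of the table, at 30814 FPKM and 11.0% of the sum, and its interval (chromosome 9, 64173387 to 64178562) overlapped the ribosomal protein gene Rpl4. The microRNA Mir703 had 5517 FPKM, and its interval (chromosome 5, 98329304 to 98802019) overlapped Cfap299 and Gm11111.

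Interferon-stimulated antiviral effectors and genes of the interferon receptor and JAK-STAT pathway were listed more often than the genes of the other lists. Of 54 interferon-stimulated antiviral effectors, 42 were listed (77.8%, against 51.7% of the genes of the other lists; adjusted p = 0.00163, Fisher's exact test). Their median was 159 FPKM, above every one of 10000 random lists of the same size drawn from the table. Of the 42 listed effectors, 26 stood at 100 FPKM or more. Medians of the JAK-STAT, NF-kB, costimulation, MHC class I and apoptosis lists also lay above all random lists of their size. Those of the housekeeping, glycolysis and cell cycle lists lay at percentiles of 99.93, 99.9 and 99.8. High medians were thus not particular to the antiviral genes. Oasl1 had 2552 FPKM, Ifitm3, which blocks virus entry, 2422, and the ubiquitin-like modifier Isg15 2186. Of 20 genes of the interferon receptor and JAK-STAT pathway, 18 were listed (adjusted p = 0.00397, Fisher's exact test), with a median of 105 FPKM. The transcription factor genes Irf7 and Irf5 had 487 and 466 FPKM, and the kinase gene Jak2 290.4. Of 20 type I and III interferon genes, 1 was listed, a lower share than among the other lists (adjusted p = 6.14e-05, Fisher's exact test), a call lost against all RefSeq protein-coding genes (adjusted p = 0.135). That gene, Ifnb1, had 4.68 FPKM (chromosome 4, 88522025 to 88522794). In the nucleic acid sensing list, 14 of 19 genes were listed, which did not pass the test (adjusted p = 0.191, Fisher's exact test). The cytosolic RNA sensor genes Dhx58 and Ifih1 had 221 and 217 FPKM, the DNA receptor gene Tlr9 174, and Tlr3, which encodes a receptor for pIC, 85.7.

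All 16 genes of the NF-kB family and its feedback regulators were listed (adjusted p = 0.000455, Fisher's exact test), with a median of 172 FPKM. The inhibitor gene Nfkbia had 1401 FPKM, Relb 299 and Nfkb2 292. Of the immediate early and AP-1 factors, 18 of 24 were listed (adjusted p = 0.123, Fisher's exact test), with Dusp5 at 473 FPKM, Junb at 470.4 and Zfp36 at 196. The list of immediate early and AP-1 factors passed against 6 lists of widely expressed genes (adjusted p = 0.00614, Fisher's exact test). It also passed against all RefSeq protein-coding genes (adjusted p = 1.24e-07, Fisher's exact test). Both backgrounds have lower shares. The 6 lists were cell cycle, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, the ER and integrated stress response, and housekeeping references. Their wide expression was not measured in these cells. Oxidative phosphorylation had 2 of 21 genes listed and housekeeping references 3 of 14, which lowers this background. Passing against the 6 lists is thus weak evidence. Cytokine and chemokine genes were listed at shares near those of the other lists, 10 of 20 (adjusted p = 0.888) and 10 of 21 (adjusted p = 0.756, both by Fisher's exact test). Their medians were 66.9 and 136 FPKM, and each list held single members at very high values. Il12b, a subunit of interleukin 12, had 1562 FPKM, Il1b 386, Tnf 254 and Il6 54.3. Cxcl10, an interferon-induced chemokine, had 1795 FPKM.

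Of 20 genes of costimulation and dendritic cell maturation, 16 were listed, which did not pass the threshold (adjusted p = 0.0626, Fisher's exact test) but passed it against 6 lists of widely expressed genes (adjusted p = 0.00552) and against all RefSeq protein-coding genes (adjusted p = 1.32e-07). Their median was 173 FPKM. Besides Ccl22 and Marcksl1, the actin-bundling gene Fscn1 had 533 FPKM, the costimulatory receptor gene Cd40 516, and the ligand genes Cd86 and Cd80 186 and 152. Of the inhibitory and tolerogenic molecules, 10 of 19 were listed (adjusted p = 1, Fisher's exact test), and their median of 8.29 FPKM lay at the 39.7 percentile of random lists. Lgals9 had 108 FPKM and Socs1 44.4. Il4i1 had 230.1 FPKM in a row that carried accessions of 3 genes, so that this value cannot be assigned to Il4i1 alone.

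MHC class I presentation had 18 of 23 genes listed (adjusted p = 0.0777, Fisher's exact test) and a median of 303 FPKM. It passed the exact test with a floor of 1 FPKM (adjusted p = 0.0303), against 6 lists of widely expressed genes (adjusted p = 0.00317) and against all RefSeq protein-coding genes (adjusted p = 4.85e-08). Next to B2m, the proteasome activator gene Psme1 had 1106 FPKM and H2-D1 1105. MHC class II presentation had 10 of 16 listed (adjusted p = 0.756, Fisher's exact test) and a median of 34.9 FPKM, with H2-Ab1 at 1348, Ifi30 at 157 and the class II transactivator gene Ciita at 113. H2 genes resemble one another closely, and shared reads were not measured, so these values are given as uncertain. Of the genes that mark CD8α+ dendritic cells, 14 of 20 were listed (adjusted p = 0.269, Fisher's exact test), with a median of 37.9 FPKM. These markers passed against 6 lists of widely expressed genes (adjusted p = 0.0315) and all RefSeq protein-coding genes (adjusted p = 1.04e-05, both by Fisher's exact test). Both backgrounds have lower shares. For MHC class I and for these markers, passing against the 6 lists is weak evidence, for the reason given above. The chemokine receptor gene Xcr1 had 387 FPKM, Cd8a 292, Ly75 106 and the dead-cell receptor gene Clec9a 57.0.

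Markers of other cell types have a value only where they were listed, and the levels of the others are unknown. The 3 of 12 listed markers of the other conventional dendritic cell type had a median of 1.18 FPKM, with Klf4 at 1.85, Clec4a1 at 1.18 and Itgam at 0.176. The 4 of 12 listed plasmacytoid dendritic cell markers had a median of 2.28 FPKM, led by Tcf4 at 5.41, Lair1 at 2.60 and Pacsin1 at 1.95. The 6 of 14 listed macrophage and monocyte markers had a median of 1.65 FPKM, with Cd68 at 33.2 and Lyz2 at 5.40. These 3 lists did not pass the test of shares (adjusted p = 0.103, 0.256 and 0.578, Fisher's exact test). Lymphocyte markers had 1 of 14 listed (adjusted p = 0.00217), Lck at 1.22 FPKM in a row with accessions of 2 genes, and fibroblast and epithelial markers 1 of 11 (adjusted p = 0.0125, both by Fisher's exact test), Cdh1 at 0.772. The call on the fibroblast and epithelial list was lost against 6 lists of widely expressed genes (adjusted p = 0.190) and against all RefSeq protein-coding genes (adjusted p = 0.539), and the call on the lymphocyte list against the latter (adjusted p = 0.386, all by Fisher's exact test).

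Oxidative phosphorylation genes and housekeeping references were listed less often than the genes of the other lists. Of 21 oxidative phosphorylation genes, 2 were listed (adjusted p = 0.000217, Fisher's exact test), Ndufb8 at 130 FPKM and Atp5c1 at 108. This call was lost against all RefSeq protein-coding genes (adjusted p = 0.364, Fisher's exact test). Of 14 housekeeping references, 3 were listed (adjusted p = 0.0449, Fisher's exact test), among them B2m and Ywhaz, the latter at 491 FPKM. The call on the housekeeping list was lost with a floor of 1 FPKM (adjusted p = 0.0698, Fisher's exact test). It was also lost against the others of the 6 lists of widely expressed genes (adjusted p = 0.370) and against all RefSeq protein-coding genes (adjusted p = 1, both by Fisher's exact test). The remaining lists did not pass the test, with adjusted p from 0.172 to 1. Glycolysis had 7 of 19 listed, with Slc2a6 at 225 FPKM, Pfkp at 221 and Tpi1 at 202. Cholesterol biosynthesis had 11 of 22, with Hmgcs1 at 109 and Pmvk at 96.2. The cell cycle list had 12 of 25, with Rrm2 at 152 and Cdk1 at 114, and Ccnd1 at 166 in a row with accessions of 2 genes. Apoptosis and cell death had 17 of 25. That list passed only against 6 lists of widely expressed genes (adjusted p = 0.0315) and all RefSeq protein-coding genes (adjusted p = 2.19e-06, both by Fisher's exact test). The survival genes Bcl2a1b, Bcl2a1d and Bcl2a1a had 1614, 695 and 371 FPKM, and as reads shared between these near-identical copies were not measured, their values are given as uncertain. The ER and integrated stress response had 9 of 16, with Hsp90b1 at 244, Herpud1 at 202 and Ppp1r15a at 83.5. The nuclear receptor corepressor complex had 2 of 9, Tbl1x at 69.6 and Kdm4a at 55.9.

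Across the 26 lists, 3 were listed at a higher share than the genes of the other lists, 5 at a lower share, and 18 did not pass the test. These counts depended on the background: 16 lists were higher and 0 lower against all RefSeq protein-coding genes, and 9 were higher and 3 lower against 6 lists of widely expressed genes. The antiviral effectors, the JAK-STAT list and the NF-kB list were higher against each of the 3 backgrounds. Costimulation, MHC class I, nucleic acid sensing and the CD8α+ dendritic cell markers were higher against both of the latter backgrounds. So were apoptosis and the immediate early and AP-1 factors. For all of these, passing against the 6 lists is weak evidence. Oxidative phosphorylation and housekeeping references, with low listed shares, are among the 6 and lower that background. MHC class II, the ER stress response, cytokines, chemokines, inhibitory molecules, cell cycle and cholesterol biosynthesis were higher against RefSeq genes alone. The genes the authors tested are unknown, so a gene too weakly expressed to be tested counted as not listed, and genes are not independent replicates. Of the 21 lists with 3 or more listed genes, 14 had a median FPKM within the highest 2.5% of random lists and 0 had one within the lowest 2.5%.

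**Figure D1:**
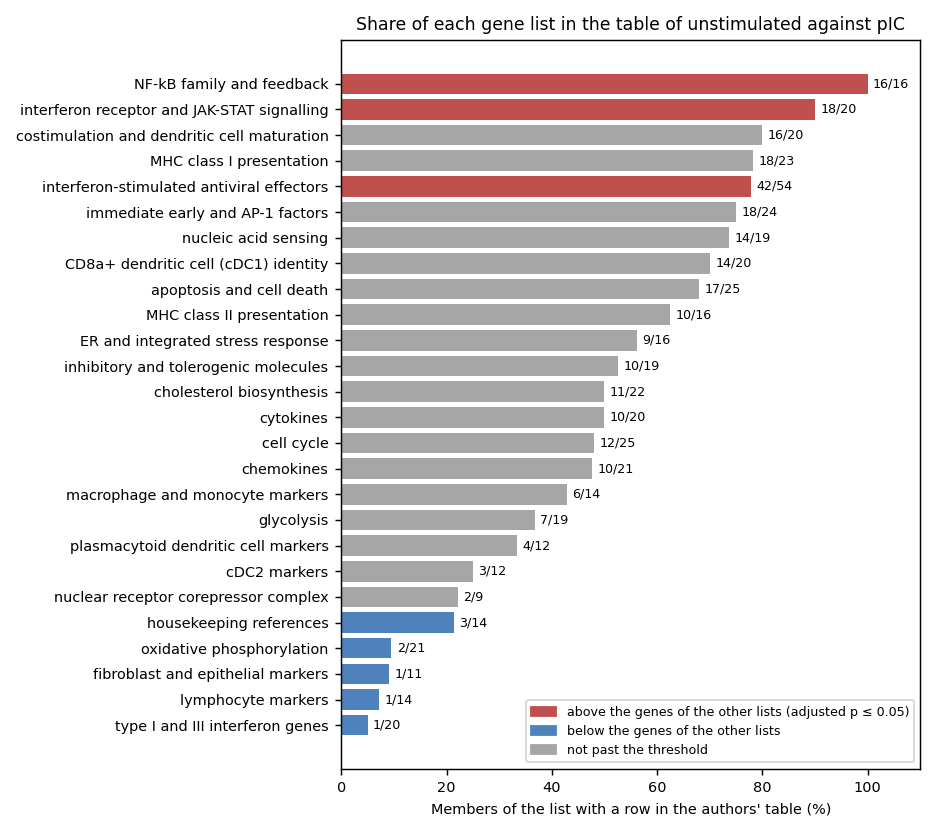
Share of the members of each gene list with a row in the authors' table, in percent on the horizontal axis, with listed and total members at the end of each bar. Red and blue bars are the 3 lists above and the 5 lists below the genes of the other lists by Fisher's exact test at an adjusted p of 0.05, and grey bars did not pass it.

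**Figure D2:**
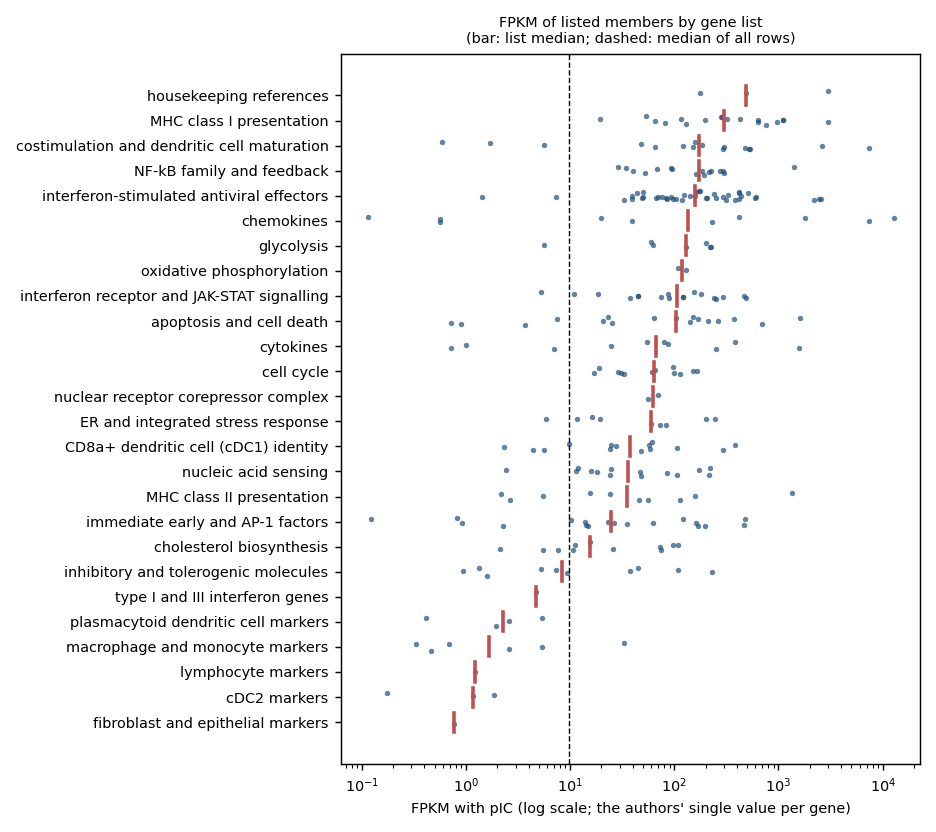
FPKM after pIC on a log axis for the listed members of each gene list, 1 point per gene, with the list's median as a red bar and the median of all rows, 9.68 FPKM, as a dashed line. The antiviral effectors, NF-kB and MHC class I lists lie mostly to the right of that line, and the listed markers of other cell types mostly to its left.

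**Figure D3:**
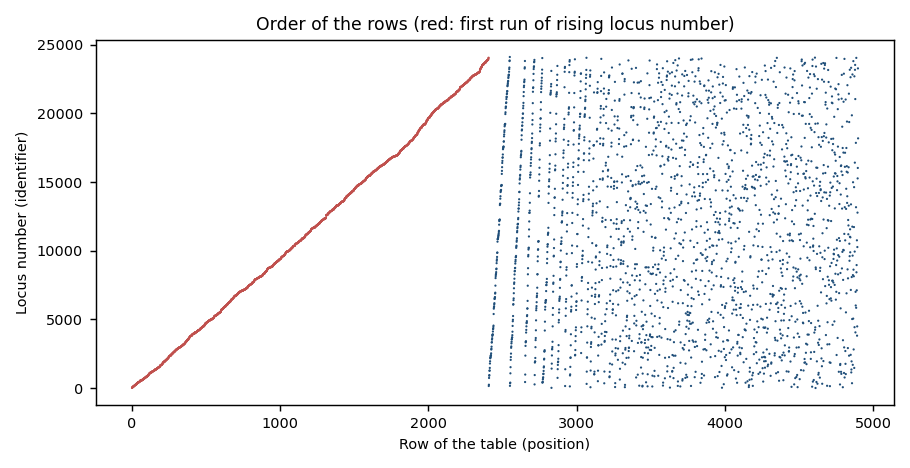
Locus number of each gene row (vertical axis, identifier) against its position in the authors' table (horizontal axis), 1 point per row. The first 2406 rows, in red, rise steadily in locus number, and the later rows, in blue, form many shorter runs.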

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

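All tests in this part were chosen after the order of the rows had been seen. What drew attention was a signal in a column the comparisons do not use: the first 2406 rows (49.1%) stand in rising order of locus number, followed by runs of 143, 102 and 64 rows and then mostly shorter ones. The table has 362 such runs, against a lowest value of 2384 in 1000 shuffled orders, and run length went down along the table (Spearman rho -0.70 across runs). A candidate explanation is that the rows were sorted by a per-gene statistic with many ties, such as a p-value with a lowest attainable level, with ties left in locus order. Sorting by FPKM is argued against by the rho of row position and FPKM across genes, -0.12. Which statistic it was stays open, and no biological explanation of the order was tested.

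In that first run, 5 of 21 lists held more of their listed members than the other rows did (Fisher's exact test, adjusted over the 21 lists): the antiviral effectors with 38 of 42 (adjusted p = 3.85e-07), costimulation and maturation with 16 of 16 (adjusted p = 0.000118), apoptosis with 15 of 17 (adjusted p = 0.00763), nucleic acid sensing with 12 of 14 (adjusted p = 0.0339) and NF-kB with 13 of 16 (adjusted p = 0.0475). Against lists matched on FPKM, in a two-sided exact test adjusted over all 21 lists, the antiviral effectors (matched mean 26.6, adjusted p = 0.00204) and costimulation and maturation (matched mean 9.90, adjusted p = 0.00721) still had more members in the run, which argues against higher FPKM as the whole cause for these lists. For apoptosis (adjusted p = 0.0836), nucleic acid sensing (adjusted p = 0.16) and NF-kB (adjusted p = 0.422, same exact test) an effect of FPKM stays open. If the order reflects a test statistic, the genes of the first run may be those with the strongest evidence of a difference, a hypothesis that this table cannot decide. Of the listed cytokines, 7 of 10 stood in the first run, but Il12b and Il1b stood in runs 165 and 361 of 362. With a floor of 1 or of 5 FPKM, the antiviral, costimulation and apoptosis lists passed the unmatched test, and the nucleic acid sensing and NF-kB lists did not.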

How the results depend on the processing

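None of the settings chosen before the data were examined could be run as written: other q or fold-change thresholds, floors on the higher of both conditions, pseudocounts, centring, expression bins and leaving out a library all need values not used here. No paired analysis was possible because there is 1 group with 1 pooled value per gene. All alternatives below were chosen after seeing the data. The 4898 rows became 3023 with a floor of 5 FPKM on the pIC value, by construction, and stayed within 1.5 times under the other 3 settings. Lists with a higher share numbered 3, against 16 with all RefSeq protein-coding genes as background and 9 with 6 lists of widely expressed genes. Lists with a lower share numbered 5, against 0 and 3 with those backgrounds. A lower background share produces this by construction. Differences in share that were negative turned positive for 11 lists against RefSeq protein-coding genes: cytokines (28.9 percentage points), chemokines (26.5), inhibitory molecules (31.6), cell cycle (26.9) and cholesterol biosynthesis (28.9), which passed the test, and markers of the other conventional dendritic cell type (3.90), plasmacytoid (12.2) and macrophage markers (21.8), glycolysis (15.8), the corepressor complex (1.12) and housekeeping references (0.324), which did not. Against the 6 lists, 6 turned positive without passing it: cytokines (11.4), chemokines (9.02), inhibitory molecules (14.04), macrophage markers (4.26), cell cycle (12.04) and cholesterol biosynthesis (14.1). Cell cycle and cholesterol biosynthesis are among the 6 and were compared with the others of the 6. Among families, 3 turned negative against the 6 lists: mitochondrial ribosomal proteins (-15.5), Trim (-10.7) and Rab genes (-8.09). Without a change of sign, 8 lists newly passed and 4 no longer passed against RefSeq genes, 6 and 2 against the 6 lists, and 1 (MHC class I) and 1 (housekeeping) with a floor of 1 FPKM; of the families, 3 and 10 against the 6 lists. The 14 lists with high medians were 12, 11 and 14 with floors of 1 and 5 FPKM and without the 2 short RNA rows. Depth is unknown, so what it limits could not be measured.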

Other observations

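The families and rows in this part, and the tests on them, were chosen after their values were seen. Of all RefSeq protein-coding genes, 21.1% were listed, a share that includes genes these cells do not express. Against that background and with adjustment over 18 families, several gene families were listed more often. The Parp family, ADP-ribosyltransferases, had 9 of 12 genes listed (adjusted p = 0.000493, Fisher's exact test here and below), the interferon-inducible Gbp family 7 of 10 (adjusted p = 0.00364) and the Slfn family 6 of 8 (adjusted p = 0.00426), though some of their members are also in the antiviral list. Genes with a Bcl2 symbol had 9 of 13 (exact test, adjusted p = 0.000919), and the sorting nexins, proteins of endosomal traffic, 18 of 30 (adjusted p = 3.68e-05) at a median of 8.97 FPKM. Intraflagellar transport genes had 8 of 14 listed (exact test, adjusted p = 0.0077), 1 of them in the first run of rows. None of these 6 calls held against 6 lists of widely expressed genes, of which 38.6% were listed (adjusted p = 0.0721 for Parp, 0.135 for Gbp, 0.102 for Slfn, 0.0826 for Bcl2 and for sorting nexins and 0.299 for intraflagellar transport, Fisher's exact test).

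Cytosolic ribosomal proteins were listed less often, 5 of 88 (adjusted p = 0.000493, and 1.34e-07 against the widely expressed lists, Fisher's exact test), as were olfactory receptors, 3 of 1110. The cell cycle list had 2 of its 12 listed genes in the first run of rows, which did not pass the adjustment over 21 lists (p = 0.0387, adjusted p = 0.116, Fisher's exact test), although the count was below that of lists matched on FPKM (matched mean 7.10, adjusted p = 0.041 over 21 lists, exact test). The 5 rows listed at 0 were Nxph4, Cmbl, Syngr1, Fam69b and Cd209e. All 5 stood in the first run, against 6 of the 46 rows above 0 and up to 0.1 FPKM (p = 0.000197, Fisher's exact test).

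Both short RNA rows are among the 20 highest, in libraries from poly(A)-selected RNA. FPKM divides by transcript length, and annotated lengths in GENCODE are 109 bases for Mir703 and 99 for Snord16a. RefSeq gives 109 bases for Mir703 and 91 for Snord16a. When FPKM was multiplied by the GENCODE length, Mir703 went from rank 4 to rank 249, so its place among the highest rows may come from division by length. Snord16a went from rank 1 to rank 13 and stayed among the 20 highest. This does not decide whether division by length raised it, because the effective length used may differ from the annotated one. Reads from Rpl4 transcripts and the effective length used by the authors' tool were not tested.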
